A study of Mus musculus with 10 samples.

How the data were processed

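Total RNA from mouse cerebral cortex was isolated with TRIzol and sequenced as paired ends of 150 bases on an Illumina NovaSeq instrument, per the labels. The 10 libraries came from separate mice, 5 with traumatic brain injury and 5 controls. The sample titles call the controls Sham while the series design calls them naive; the titles' name is used here, and whether they had surgery is not settled. The injury model, the time after injury and the strain are not given in the sources used. Groups and replicate numbers were taken from the sample titles, and 0 sample columns of the table were left unused.

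Per the submitters' processing notes, cutadapt 1.9, HISAT2 and StringTie were used with the mouse genome mm10; versions of the latter tools, the annotation release and the order of steps are not stated. The deposited table lists 55401 genes with estimated counts and FPKM for each library, named so per the file headers. The deposited estimated counts are whole numbers, and 42.6% of the values from 1 to 12 were 4, 8 or 12 where an even spread gives 25%. In 99.7% of 932 single-transcript genes with many counts the ratio of count to FPKM was constant within 1% after 1 factor per library. About 4 counts therefore appear to stand for 1 sequenced fragment, and the totals of 47.6 to 71.3 megacounts for 11.9 to 17.8 M fragments; the counting tool is not stated. The deposited FPKM values are given per kilobase of transcript and scaled to the library's fragments by the authors, and FPKM listed at the table's lowest fill value go with a count of 0 and were read as 0. A count of 0 in all libraries was found for 22549 genes. Gene IDs were matched to GENCODE M21, where 99.5% were found, 94.2% of these at the same position; gene types are from that annotation.

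Genes with an FPKM of at least 0.5 in at least 5 of the 10 libraries were tested, 16316 in all. Counts were compared between TBI and Sham with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test, group only, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The common biological coefficient of variation was 20.9%. The plan was a limma-trend test of log2(FPKM + 1) unless whole-number counts were present, in which case edgeR applied; that limma test (limma 3.58.1) was run as an alternative, and 602 of the 659 called genes passed it too in the same direction. The SE of a log2 change is the absolute change over the square root of F and is approximate. Levels are FPKM means ± SD, n = 5. For a gene with 0 counts in all libraries of a group the fold is a lower bound against 3 fragments, taken as 12 counts over the group, and for genes with up to 12 counts in a group the ratio is given with an exact 95% interval. For that ratio the group's counts were divided by 4, rounded to whole fragments and scaled to the total counts of the groups. Intervals and floors cover counting error only.

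The 35 gene lists were tested with camera on the same counts and the dispersions of the edgeR fit (preset correlation 0.01, Benjamini-Hochberg over the lists). An estimated correlation and fry were set beside it. The estimated setting also raised the adjusted p of lists whose correlation was below 0 or could not be estimated. A call lost under it is therefore not put down to correlation alone. In DESeq2 and the limma alternatives camera ran on log2 values. The fry p tests whether a list's genes move on balance in 1 direction and does not compare the list with other genes. Members past the threshold were counted over all tested genes and adjusted over the list alone. GO and KEGG terms as the table pairs them with genes were tested the same way where 10 to 300 tested genes carried them. Named genes were the 12 largest rises and 12 largest falls on the log2(FPKM + 1) scale among called genes with a mean of at least 1 FPKM in a group, no overlap between the groups and no clone-like symbol, and up to 4 called members of each list with the largest change, or the 2 with the smallest p where none passed. Other list members cited as not having passed, and Fabp5, P2ry12, Tmem119, Fos and Jun, were picked after their values were seen. Some genes that the rule picked are not reported here. Groups of libraries were also compared on totals and shares with exact two-sided permutation tests; with 5 against 5 the smallest p these can give is 0.0079. Lists, named-gene rule, tests and most alternatives were fixed before the data were examined.

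Alternatives were no filter, a filter of 2 FPKM, DESeq2 size factors, DESeq2 1.42.0, limma with a pseudocount of 0.1, TPM, median-of-ratios or quantile scaling, no trend, robust fitting, array weights, an exact rank-sum test, a block for the replicate number, and leaving out each library. Counts divided by 4, limma-trend on log2(FPKM + 1), edgeR with the replicate block and leaving out small RNA genes were added after seeing the data. On data simulated over 16316 genes, edgeR called 40 of 100 genes changed 1.5-fold and 100 of 100 changed 3-fold, with 10 false calls among the others, so smaller changes are often missed at this depth and n. The changed genes were drawn above a minimum mean count. Genes were simulated independently, on the scale of the deposited counts, with the spread fitted as a trend over genes. The shares recovered therefore do not cover the lowest genes or genes noisier than that trend. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.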

Results

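The data were gene-level RNA sequencing values from the cerebral cortex of 10 mice, 5 after traumatic brain injury (TBI) and 5 controls that the sample titles call Sham. Each library was a separate mouse, so n = 5 in each group, and ± after an FPKM value is the SD of those 5 libraries. Total estimated counts per library, in megacounts (M), were 47.6, 70.5, 69.3, 51.5 and 62.1 M for TBI replicates 1 to 5, and 59.4, 61.8, 63.9, 62.8 and 71.3 M for Sham replicates 1 to 5. Mean totals were 60.2 ± 10.3 M in TBI and 63.8 ± 4.48 M in Sham, a difference that did not pass an exact two-sided permutation test (p = 0.444). Of 55401 annotated genes, 16316 passed the expression filter and were tested.

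The comparison addressed which genes of the cortex differ in level between injured and control animals, in a study whose title links the brain transcriptome after TBI with the gut microbiota. Injured cortex had higher levels of genes of activated microglia, reactive astrocytes, complement, interferon response and antigen presentation. Gfap, the intermediate filament of astrocytes, rose from 38.3 ± 6.0 to 259.7 ± 67.4 FPKM, and the lysozyme gene Lyz2 of myeloid cells rose from 5.02 ± 0.621 to 67.3 ± 31.7 FPKM. Some genes fell by smaller amounts, 6 of 15 of cholesterol synthesis and 3 of 15 of recent neuronal activity, and neither list passed with an estimated correlation (camera adjusted p = 0.0644 and 0.117). The sterol enzyme Hmgcs1 was at 37.8 ± 2.85 against 54.2 ± 2.72 FPKM and the neuronal transcription factor Npas4 at 2.16 ± 0.687 against 6.76 ± 2.01 FPKM. The fixed lists of oligodendrocyte, inhibitory neuron and serotonin genes held no called gene among the tested members, while Cort, a neuropeptide gene of interneurons outside those lists, was lower.

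In edgeR, 582 genes were higher and 77 were lower in TBI at an adjusted p under 0.05, so 88.3% of the called genes were higher. A fold of 2 or more was reached by 238 of the higher and 5 of the lower genes. At an unadjusted p under 0.05 there were 2445 genes. The 5 TBI and 5 Sham values did not overlap for 616 of the called genes, and for 6.33% of all tested genes against 0.794% given by chance. The first principal component carried 24.7% of the variance and parted the groups, with TBI libraries from -24.7 to -4.96 and Sham libraries from 10.3 to 16.8. With 1 library left out at a time the number of higher genes ranged from 441 to 659. The number of lower genes was 37, 42, 41 and 47 without TBI replicates 1, 2, 3 and 5, 45, 42 and 45 without Sham replicates 1, 2 and 3, and up to 84 without Sham replicate 4. Lower genes with a fold of 2 or more numbered 9 without TBI replicate 4 and 8 without Sham replicate 4.

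**Figure D1:**
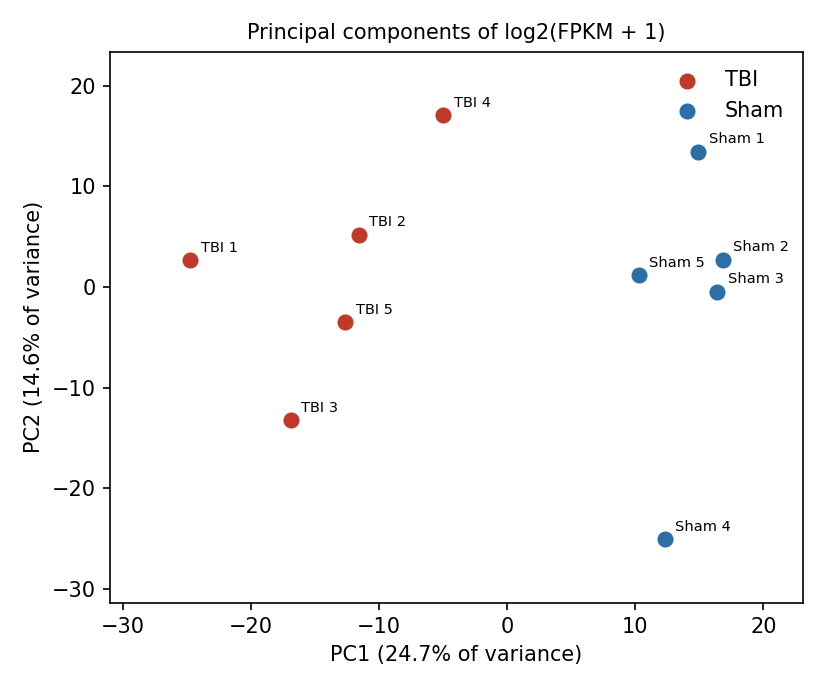
Principal components 1 and 2 of log2 expression over the 16316 tested genes, each point being 1 library coloured by group, with the share of variance on each axis. TBI libraries lie between -24.7 and -4.96 on component 1 and Sham libraries between 10.3 and 16.8.

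Among the largest rises, Cst7, which encodes a cystatin of activated microglia, went from 0.0575 ± 0.0596 to 8.51 ± 4.39 FPKM (log2 fold change 7.04, approximate SE 0.64, edgeR adjusted p = 3.3e-04). Its Sham level rests on 22 counts over the 5 libraries. Serpina3n (chromosome 12, 104406729 to 104414329), a secreted protease inhibitor, rose 8.34-fold from 4.30 ± 0.664 to 36.9 ± 12.9 FPKM (adjusted p = 2.5e-04). Gfap (ENSMUSG00000020932, mm10 chromosome 11, 102887336 to 102897200) rose 6.61-fold (log2 2.72, approximate SE 0.19, adjusted p = 2.5e-04). Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) rose 13.1-fold (log2 3.71, approximate SE 0.34, adjusted p = 3.3e-04). The interferon-induced gene Ifi27l2a rose 11.3-fold to 11.5 ± 5.08 FPKM, the complement gene C4b 7.91-fold to 16.1 ± 5.59 FPKM, and Gpnmb, a membrane glycoprotein of lipid-laden phagocytes, 17.5-fold to 6.37 ± 3.91 FPKM. Clec7a, a receptor for fungal glucans, rose from 0.0689 ± 0.0386 to 4.28 ± 2.00 FPKM, and the pore-forming macrophage gene Mpeg1 from 5.92 ± 0.571 to 29.7 ± 10.1 FPKM. Spp1, which encodes osteopontin, rose from 6.85 ± 1.12 to 36.8 ± 19.3 FPKM, and the secreted galectin ligand Lgals3bp from 2.84 ± 0.264 to 19.3 ± 12.2 FPKM. Cd5l, a secreted macrophage protein, had 0 counts in all Sham libraries and 3.30 ± 2.08 FPKM in TBI, at least 197-fold higher against a floor of 12 counts over the group (adjusted p = 0.0017).

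**Figure D2:**
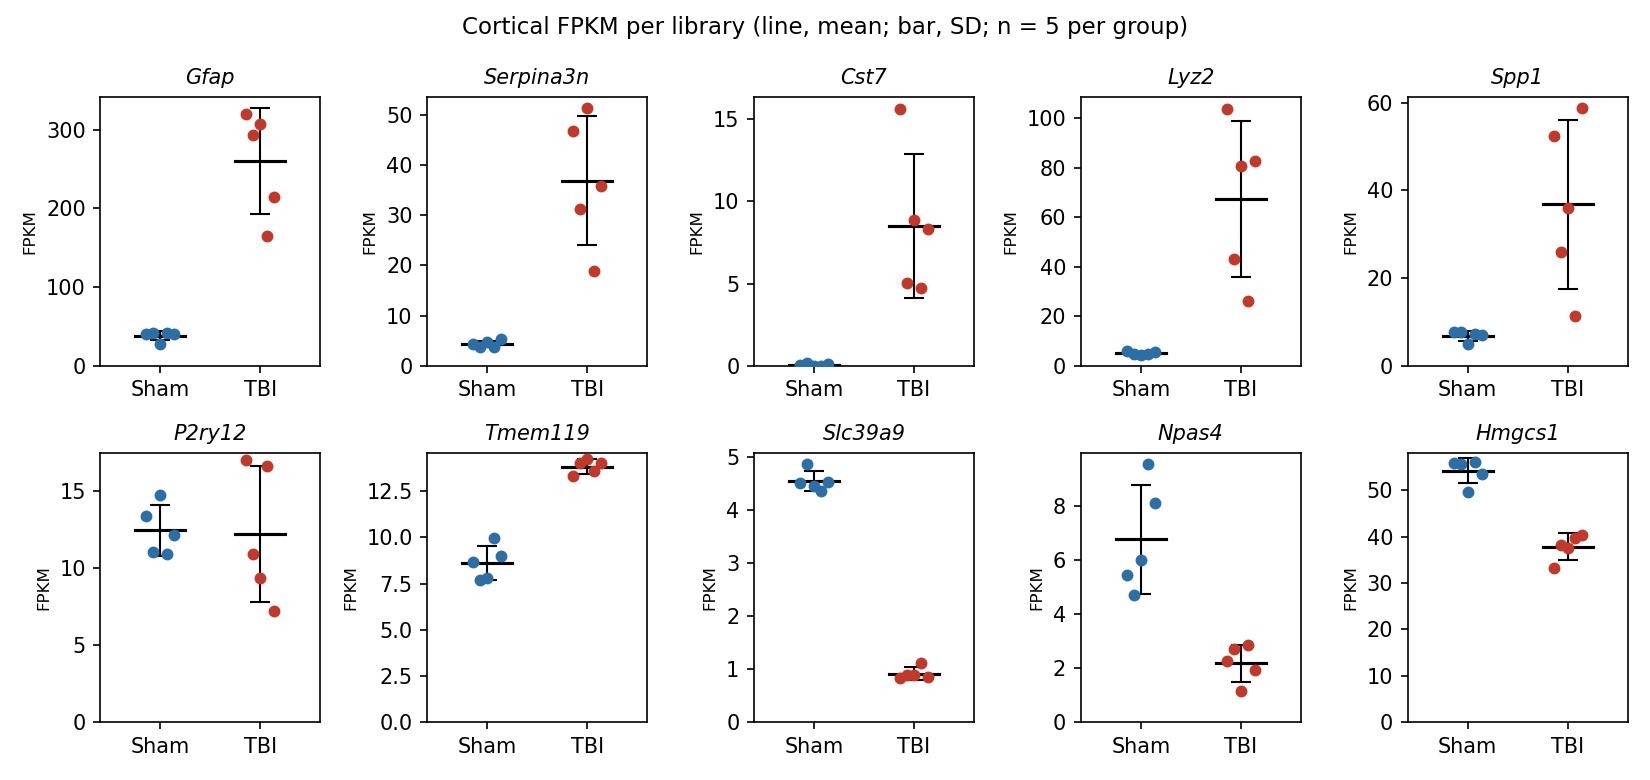
FPKM (linear axis from 0) of 10 genes per library, each point being 1 library, with the group mean as a line and the SD as an error bar, n = 5 each. Gfap, Serpina3n, Cst7, Lyz2, Spp1 and Tmem119 are higher and Slc39a9, Npas4 and Hmgcs1 lower in TBI, while P2ry12 is at 12.2 ± 4.40 FPKM in TBI and 12.4 ± 1.64 FPKM in Sham.

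Activated microglia genes had the smallest camera p of the 35 lists with the preset correlation (median log2 change 1.71, camera adjusted p = 6.8e-52). Of 17 tested members 16 rose and 0 fell, with 16 also adjusted over the list alone. With the list's estimated correlation of 0.559 the camera adjusted p was 0.0029, a value that other lists shared. Cst7, Clec7a, Gpnmb and Lgals3 led the list, Lgals3 going from 0.141 ± 0.0920 to 2.57 ± 1.27 FPKM, and the lipid chaperone Fabp5 did not pass. Homeostatic microglia markers also rose in 8 of 12 members (10 adjusted over the list alone, median 0.77, adjusted p = 1.9e-26). Fcrls went from 10.1 ± 0.372 to 31.3 ± 6.48 FPKM, the growth factor receptor Csf1r from 13.8 ± 0.731 to 31.4 ± 4.40, and Gpr34 from 4.28 ± 0.384 to 9.54 ± 2.10. P2ry12, the purinergic receptor of resting microglia, did not pass (adjusted p = 0.93), and neither did Siglech, Selplg and Olfml3. Of 7 monocyte and macrophage markers, Lyz2 and Ms4a6d (0.502 ± 0.112 to 1.86 ± 0.443 FPKM) rose and 5 did not pass, among them Ly6c2 and Mrc1 (5 rose adjusted over the list alone, median 0.65, adjusted p = 1.1e-09). The neutrophil list had 1 tested member and is a single-gene test: the cytokine receptor Csf3r rose from 1.5 ± 0.333 to 5.5 ± 1.28 FPKM (list adjusted p = 2.3e-07). The lymphocyte list also had 1 tested member, Cd4, which did not pass at 3.42 ± 1.59 against 3.53 ± 2.44 FPKM (list adjusted p = 0.922).

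Pan-reactive astrocyte genes rose in 9 of 11 members (11 adjusted over the list alone, median 1.29, camera adjusted p = 1.3e-36). The chemokine Cxcl10 went from 0.0306 ± 0.0206 to 2.12 ± 1.18 FPKM and the protease inhibitor Timp1 from 0.468 ± 0.191 to 1.9 ± 0.525, while Hspb1 and Cp did not pass. Of 10 A1-type reactive genes 5 rose, 0 fell and 5 did not pass (6 rose adjusted over the list alone, median 0.75, adjusted p = 7.4e-11). The guanylate-binding protein gene Gbp2 rose from 1.22 ± 0.327 to 3.67 ± 1.27 FPKM and the class I histocompatibility gene H2-D1 from 13.9 ± 1.72 to 39.2 ± 12.6, while Amigo2 and Fkbp5 did not pass. Of 6 A2-type genes the endotoxin co-receptor Cd14 rose from 0.862 ± 0.133 to 3.03 ± 1.07 FPKM and the prostaglandin synthase Ptgs2 fell from 2.48 ± 0.339 to 1.81 ± 0.151 (3 rose and 1 fell adjusted over the list alone). That list as a whole did not pass (median 0.34, adjusted p = 0.0502). Values from whole tissue do not show which cells the transcripts of these astrocyte lists came from. Homeostatic astrocyte markers rose in 2 of 14 members (7 adjusted over the list alone, median 0.25, adjusted p = 4.2e-05), and the list call was lost at adjusted p = 0.0644 with an estimated correlation. The water channel Aqp4 rose from 18.8 ± 2.12 to 32.0 ± 4.45 FPKM and Mlc1 from 45.9 ± 4.73 to 62.2 ± 2.69, while the glutamate transporter Slc1a2 and S100b did not pass. Values of Slc1a2 lay on 2 separate levels, with 3 TBI and 4 Sham libraries on the lower one, so its result decides little.

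Of 14 complement genes 8 rose and 0 fell (11 rose adjusted over the list alone, median 1.17, camera adjusted p = 2.4e-36). The receptor C3ar1 rose from 0.479 ± 0.0910 to 2.60 ± 1.09 FPKM, the classical pathway gene C1qb from 32.0 ± 3.16 to 124 ± 36.5, and the integrin Itgb2 from 1.27 ± 0.108 to 4.80 ± 1.02. Interferon-stimulated genes rose in 12 of 15 members (14 adjusted over the list alone, median 1.82, adjusted p = 3.7e-36). Bst2, a restriction factor at the cell surface, went from 2.37 ± 0.489 to 11.8 ± 4.53 FPKM, Oas1a from 0.439 ± 0.157 to 2.14 ± 0.691, and the transcription factor Irf7 from 0.451 ± 0.156 to 1.93 ± 1.05. Antigen presentation genes rose in 8 of 11 members (11 adjusted over the list alone, median 1.28, adjusted p = 6.2e-24). The endosomal protease Ctss went from 37.3 ± 2.30 to 131 ± 36.2 FPKM, and the class II genes H2-Ab1 and H2-Aa rose 3.11-fold and 2.91-fold. Microbial sensing genes rose in 6 of 12 members (10 adjusted over the list alone, median 0.89, adjusted p = 1.3e-15), though the list did not pass with members of at least 2 FPKM alone (adjusted p = 0.0826). Tlr2, a receptor for bacterial lipoproteins, rose from 0.257 ± 0.0986 to 1.76 ± 0.831 FPKM and its partner Tlr1 from 0.151 ± 0.0651 to 0.813 ± 0.347, while Tlr13 and Tlr7 also rose and Myd88, Nod1 and Casp1 did not pass.

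Of 8 tested cytokine and chemokine genes 7 rose, 7 also adjusted over the list alone (median 2.54, camera adjusted p = 5.9e-22), and the alarmin Il33 did not pass. Of the 20 fixed members, others such as Il1b, Il6 and Tnf lay below the expression filter, while Ccl5 met it through TBI libraries alone. In the fit without a filter 8 of 19 members rose, 0 fell and 11 did not pass. Ccl12, a monocyte attractant, rose from 0.440 ± 0.279 to 3.70 ± 1.14 FPKM. Ccl3 rose from 0.108 ± 0.139 to 2.35 ± 1.38 FPKM, a log2 change of 4.28 that became 5.31 without Sham replicate 5. Ccl4 had 184 counts in TBI and 4 in Sham, a ratio of 48.8 (95% exact interval 8.33 to 1968), and all its Sham counts lay in Sham replicate 1. Ccl5 had 501 counts in TBI and 7 in Sham, a ratio of 66.3 in rounded fragments scaled to the group totals (95% exact interval 18.0 to 553). All its Sham counts were in Sham replicate 2, and it was at 4.30 FPKM in TBI replicate 1 against 0.754 to 1.16 in the other TBI libraries. The fitted log2 change of Ccl5, 6.18, was 5.46 without TBI replicate 1 and 9.78 without Sham replicate 2, and that of Ccl4, 5.37, was 8.25 without Sham replicate 1. Leaving out either Sham library leaves 0 Sham counts, so 9.78 and 8.25 are no bound. Oxidative stress and metallothionein genes rose in 7 of 18 members (11 adjusted over the list alone, median 0.39, adjusted p = 3.1e-13). The oxidase subunit Cyba went from 2.35 ± 0.642 to 7.72 ± 0.998 FPKM, Ncf4 from 0.317 ± 0.0773 to 1.03 ± 0.240, and the heme-degrading enzyme Hmox1 from 2.64 ± 0.360 to 7.73 ± 2.22, while Sod2 and Gpx4 did not pass.

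**Figure D3:**
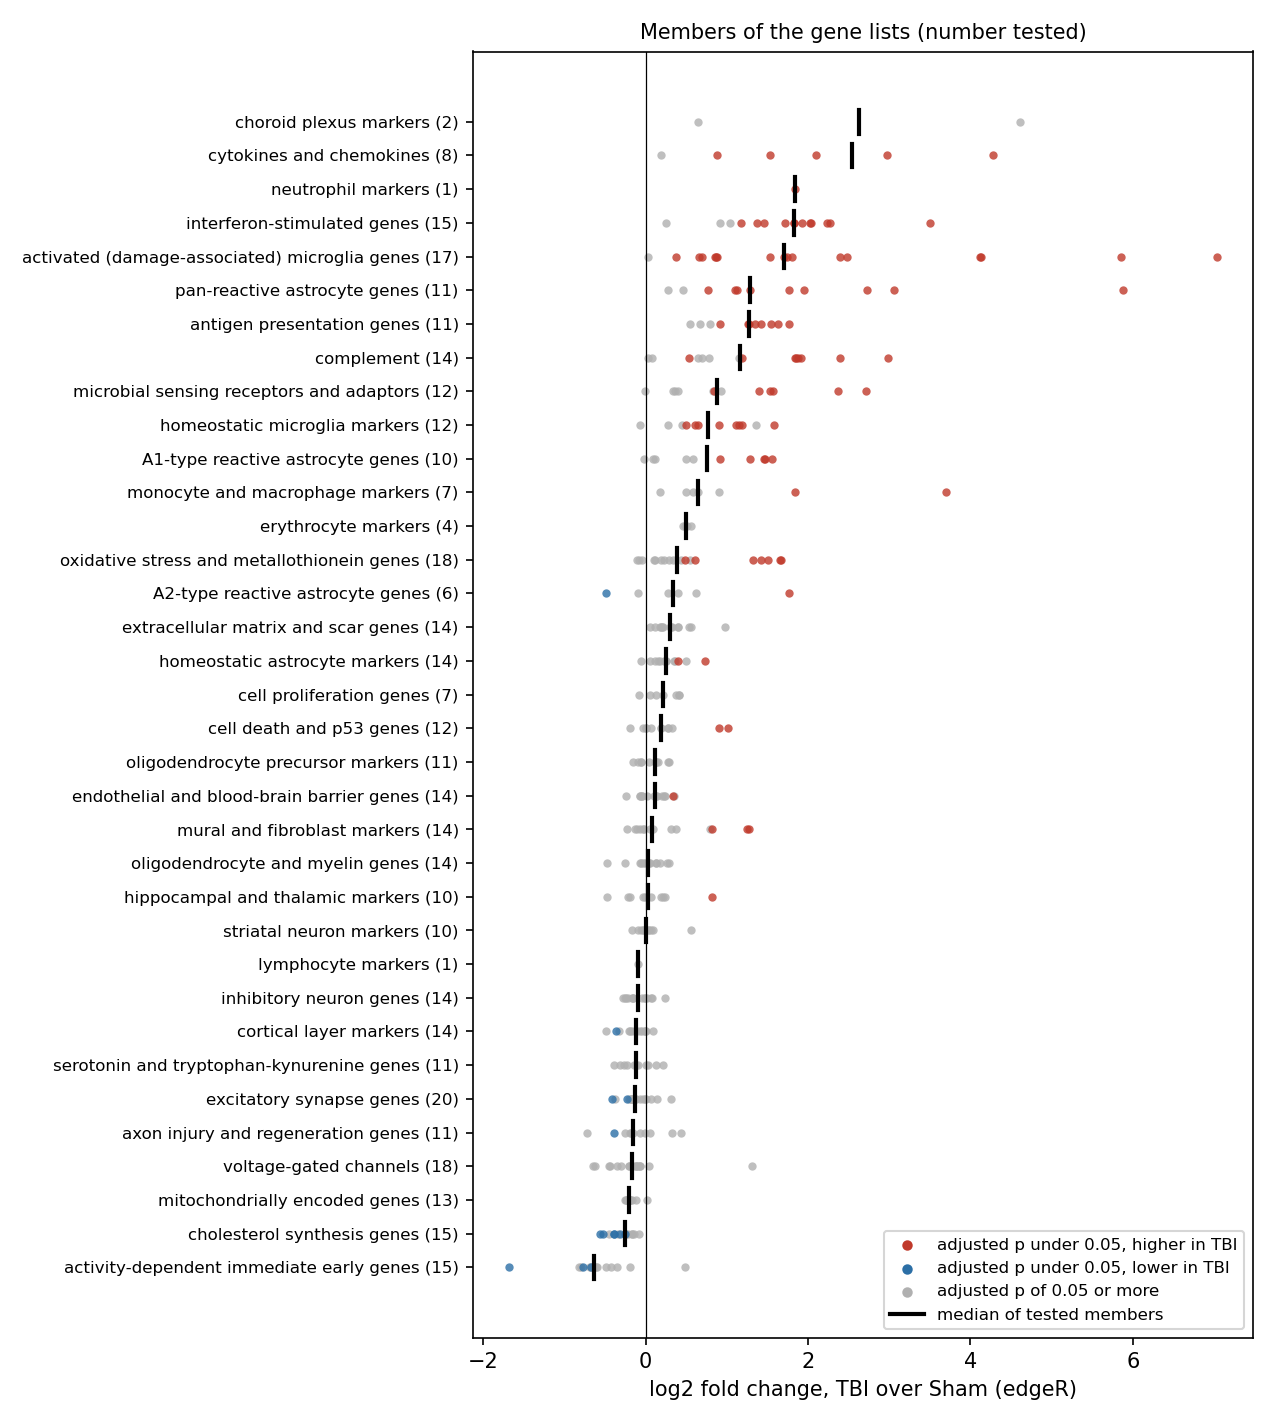
Log2 fold change, TBI over Sham, of the tested members of 35 fixed gene lists, each point being 1 gene and the bar the list median. Red points are genes past the threshold and higher, blue points past it and lower, and Ccl4 and Ccl5 are not drawn because their Sham counts are near 0; medians run up to 2.54 for cytokines, apart from the choroid plexus list of 2 genes, whose median rests on TBI replicate 1, and down to -0.63 for immediate early genes.

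Slc39a9 (ENSMUSG00000048833, mm10 chromosome 12, 80643883 to 80683342), a zinc transporter gene, had the largest fall and the smallest adjusted p of the named genes. Its level was 0.912 ± 0.115 FPKM in TBI and 4.54 ± 0.196 in Sham, 5.10-fold lower (log2 -2.35, approximate SE 0.08, edgeR adjusted p = 3.6e-07). Across the tested genes 121 others also sat on 2 separate levels, with low libraries in both groups, and 9 others, all called higher in TBI, followed the groups. Cort, which encodes the neuropeptide cortistatin of cortical interneurons, was 3.26-fold lower at 2.41 ± 1.05 against 7.67 ± 2.34 FPKM (adjusted p = 0.012). The ubiquitin ligase subunit Fbxo33 was 2.36-fold lower, the long noncoding RNA Mir124-2hg 1.92-fold lower, and the bromodomain gene Trim66 1.89-fold lower. The transferrin receptor Tfrc fell from 15.5 ± 1.36 to 10.2 ± 1.11 FPKM, the prohormone convertase Pcsk1 from 8.26 ± 1.66 to 5.30 ± 0.291, and the small GTPase Diras2 from 65.0 ± 7.97 to 44.8 ± 7.22. The call of Diras2 was lost without TBI replicate 1, TBI replicate 4, Sham replicate 3, Sham replicate 4 or Sham replicate 5 (adjusted p = 0.0556, 0.0659, 0.0762, 0.0643 and 0.0553).

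Immediate early genes of neuronal activity fell in 3 of 15 members and rose in 0, with 8 lower and 1 higher adjusted over the list alone (median -0.63, camera adjusted p = 2.3e-09), a list call lost at adjusted p = 0.117 with an estimated correlation. Npas4 was 3.21-fold lower (adjusted p = 0.0041), Egr1 fell from 69.6 ± 15.7 to 41.8 ± 5.70 FPKM (adjusted p = 0.013), and the growth factor Bdnf from 4.27 ± 0.730 to 2.76 ± 0.315 (adjusted p = 0.0085). Fos did not pass (6.05 ± 1.25 against 10.4 ± 3.13 FPKM, adjusted p = 0.071) and neither did Jun. Cholesterol synthesis genes fell in 6 of 15 members and rose in 0 (10 lower adjusted over the list alone, median -0.26, adjusted p = 5.9e-11), and this list call was lost at adjusted p = 0.0644 with an estimated correlation. Hmgcs1 (adjusted p = 5.9e-04) was joined by the squalene epoxidase Sqle, from 9.87 ± 0.925 to 7.75 ± 0.433 FPKM. Rescaled to TPM, Sqle lost its call in limma (adjusted p = 0.0644).

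Excitatory synapse genes fell in 2 of 20 members, also 2 adjusted over the list alone (median -0.14, camera adjusted p = 0.0028), and the list call was lost at adjusted p = 0.164 with an estimated correlation. Among them was the active zone gene Rims1, 23.03 ± 2.08 against 29.9 ± 3.06 FPKM. Voltage-gated channel genes had 0 called members of 18, and 0 adjusted over the list alone, with a median of -0.17 and an adjusted p of 0.0034 that was adjusted p = 0.190 with an estimated correlation. The potassium channel Kcnc2 had the smallest p there. Of 14 inhibitory neuron genes 0 passed, and 0 adjusted over the list alone (median -0.10, adjusted p = 0.121), Sst coming nearest. Of 14 cortical layer markers Etv1 fell, from 4.03 ± 0.450 to 3.22 ± 0.187 FPKM (median -0.12, adjusted p = 0.0382), and this list call was lost at adjusted p = 0.118 with an estimated correlation. Without TBI replicate 2, TBI replicate 4, Sham replicate 3 or Sham replicate 4 the layer list did not pass (adjusted p = 0.135, 0.0709, 0.0588 and 0.0507). Of 11 axon injury and regeneration genes the neuropeptide receptor Npy1r fell from 7.43 ± 0.522 to 5.81 ± 0.364 FPKM, with 1 higher and 1 lower adjusted over the list alone (list median -0.16, adjusted p = 0.153), and Gap43 and Sox11 did not pass. The list had 4 further members below the expression filter, of which 2 rose and 0 fell in the fit without a filter. Mean FPKM in TBI and Sham were 1.40 and 0.300 for Atf3, 1.37 and 0 for Sprr1a, and 0.436 and 1.31 for Gal.

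Mitochondrially encoded genes had 0 called members of 13 and 0 adjusted over the list alone. The list passed (median -0.20, camera adjusted p = 9.2e-05), but its call was lost at adjusted p = 0.301 with an estimated correlation and at 0.212 after quantile normalization. The share of counts from these genes was 9.33 ± 0.635% in TBI and 10.2 ± 0.731% in Sham, a difference that did not pass an exact permutation test (p = 0.0794). Serotonin and tryptophan-kynurenine genes had 0 called members of 11, also 0 adjusted over the list alone (median -0.12, adjusted p = 0.277), Htr1a and the amine oxidase Maob coming nearest.

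Of 14 mural and fibroblast markers the fibrillar collagen genes Col1a1 (1.64 ± 0.305 to 4.0 ± 0.899 FPKM), Col3a1 (0.604 ± 0.103 to 1.5 ± 0.319) and Col1a2 (1.47 ± 0.155 to 2.66 ± 0.556) rose, with 4 adjusted over the list alone. The mural list passed (median 0.08, camera adjusted p = 0.0014), a call lost at adjusted p = 0.284 with an estimated correlation, while Acta2 and Pdgfrb did not pass. Extracellular matrix and scar genes had 0 called members of 14 and 6 higher adjusted over the list alone (median 0.31, adjusted p = 2.7e-04), a call lost at adjusted p = 0.0872 with an estimated correlation. Col6a1 and Fn1 came nearest there. Of 14 endothelial and blood-brain barrier genes the vascular cadherin Cdh5 rose from 3.51 ± 0.232 to 4.56 ± 0.372 FPKM, and the list did not pass (median 0.12, adjusted p = 0.138). Of 12 cell death and p53 genes Casp8 (0.903 ± 0.177 to 1.87 ± 0.256 FPKM) and the tumour necrosis factor receptor Tnfrsf1a (3.17 ± 0.166 to 6.08 ± 0.907) rose, 2 also adjusted over the list alone. That list passed (median 0.19, adjusted p = 0.0044), a call lost at adjusted p = 0.0660 with an estimated correlation, and Cdkn1a and Bax did not pass.

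Oligodendrocyte and myelin genes had 0 called members of 14 (median 0.03, camera direction down, adjusted p = 0.922), Opalin and Mal coming nearest. Oligodendrocyte precursor markers had 0 of 11 (median 0.12, adjusted p = 0.543), Bmp4 and Sox10 coming nearest, and proliferation genes 0 of 7 with 1 higher adjusted over the list alone (median 0.21, adjusted p = 0.157), Mcm6 and Plk1 coming nearest. Erythrocyte markers had 0 of 4 (median 0.50, adjusted p = 0.121), among them Hbb-bt and Hbb-bs, and the 2 tested choroid plexus markers, Ttr and Clic6, did not pass (median 2.63, adjusted p = 0.717). Ttr was at 852.9 FPKM in TBI replicate 1 and from 0.240 to 27.6 FPKM in the other 9 libraries. Without TBI replicate 1 the log2 change of Ttr went from 4.62 to -3.02 and that of Clic6 from 0.64 to 0.08, so the list median rests on that library; without Sham replicate 3 Ttr was at 6.85. Striatal neuron markers had 0 of 10 (median 0.01, adjusted p = 0.922), and here too the median and the camera direction differed in sign. Of 10 hippocampal and thalamic markers the kinase Prkcd rose from 1.80 ± 0.344 to 3.27 ± 0.481 FPKM, and the list did not pass (median 0.03, adjusted p = 0.552). Adjusted over the list alone, the counts were 0 for the myelin, precursor, erythrocyte, choroid plexus and striatal lists, and 1 each for the endothelial, hippocampal and cortical layer lists, as over all genes.

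In camera with the preset correlation 16 of the 35 lists were higher and 6 lower in TBI, and with an estimated correlation 12 were higher and 0 lower. The camera adjusted p of those 12 then ran from 0.0029 to 0.0092, above the values given for them with the preset correlation. That rise is not from correlation alone. The neutrophil list, 1 gene with no correlation to estimate, went from a camera adjusted p of 2.3e-07 to 0.0029. Monocyte and macrophage markers, with an estimated correlation of -0.027, went from 1.1e-09 to 0.0029. Those 12 were the lists of pan-reactive and A1-type astrocytes, both microglial lists, monocytes and macrophages, Csf3r alone for neutrophils, cytokines, complement, interferon-stimulated genes, antigen presentation, microbial sensing and oxidative stress. Of 299 KEGG terms 81 were higher and 4 lower, and 30 higher and 0 lower with an estimated correlation. In the Phagosome term 29 of 113 genes rose and 1 fell (adjusted p = 0.0398 with an estimated correlation), and in Complement and coagulation cascades 12 of 32 rose (adjusted p = 0.0327 with an estimated correlation). Of 1937 GO terms 98 were higher and 7 lower, and 0 either way with an estimated correlation.

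Calls of 4 further named genes were lost when 1 library was left out. Ptgs2 lost its call without TBI replicates 1 and 5 and Sham replicates 1 and 2 (adjusted p = 0.0636, 0.0668, 0.0523 and 0.0625), and Etv1 without TBI replicates 1, 3 and 5 and Sham replicate 1 (0.0725, 0.0727, 0.0689 and 0.0670). Rims1 lost it without TBI replicates 1, 2 and 4 and Sham replicates 2 and 3 (0.0646, 0.0676, 0.0540, 0.0654 and 0.0631). Cdh5 lost it without TBI replicates 1, 2, 3 and 5 and Sham replicates 1, 2, 3 and 5 (0.0693, 0.0759, 0.0573, 0.0788, 0.0797, 0.0514, 0.0690 and 0.0803). Genes of the H2 family, Oas1a, the globins and the mitochondrial genes have close relatives in sequence with which reads can be shared.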

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

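Among the tests in this part, the count of other splits and the test of genes on 2 levels were fixed before their results were seen, and the others (neighbouring genes, the chromosome 12 stretch, microglial and blood cell markers, choroid plexus markers) were chosen after the result was seen.

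In 198 groups of 5 libraries, 23 had a library far from the other 4, where chance gives about 1 in 20, or 9.9, for independent normal values. The genes share the same 10 libraries and their FPKM need not be normal, so 23 against 9.9 does not establish an excess. The Sham flags of Ccl4 and Ccl5 rest on 4 and 7 counts. Of these 14 were in Sham and 9 in TBI, and Sham replicates 2 and 3 held 5 each, TBI replicate 4 held 4 and TBI replicate 1 held 3. In TBI replicate 1, Lgals3bp was at 40.3 FPKM (9.53 to 18.1 in the other TBI libraries), Ccl5 at 4.30 (0.754 to 1.16) and Ttr at 852.9 (0.240 to 1.92). In TBI replicate 4, Slc39a9 was at 1.12 (0.831 to 0.880), Aqp4 at 24.1 (33.4 to 34.6), Plk1 at 0.765 (1.02 to 1.09) and Prkcd at 2.44 (3.32 to 3.64). Bdnf stood apart in TBI replicate 2 at 3.31 (2.54 to 2.73) and Mir124-2hg in TBI replicate 3 at 6.06 (3.06 to 3.91). In Sham replicate 3, Gfap was at 27.6 (40.2 to 41.9 in the other Sham libraries), Spp1 at 4.93 (6.91 to 7.64), Col3a1 at 0.421 (0.643 to 0.661), Ncf4 at 0.182 (0.339 to 0.377) and Ttr at 27.6 (0.317 to 3.84). In Sham replicate 2, Ccl5 was at 0.0822 (0 in the others), Bmp4 at 2.20 (1.76 to 1.82) and mt-Nd1 at 6819 (7978 to 8295), the pseudogene share was 4.99% (5.57 to 5.75%) and the share of the 10 most abundant genes 8.61% (10.1 to 10.5%). Sham replicate 1 stood apart for Ccl4 at 0.0848 (0 in the others), Sham replicate 4 for Mir124-2hg at 6.64 (7.73 to 7.88), and Sham replicate 5 for Tap1 at 0.409 (0.261 to 0.290) and Tlr2 at 0.429 (0.180 to 0.233).

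Of 100 splits of the 10 libraries into 5 and 5, drawn with the real one among them, 1 split, the real one, gave as many called genes (659), and the highest other split gave 7. Chance in the grouping of the libraries is thereby argued against as the source of the count, at 1 in 100, the smallest share these splits can give. The other splits mix TBI and Sham libraries, and genes that differ between the groups then spread more within each part. The gap between 659 and 7 therefore does not measure how many calls chance alone gives.

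Slc39a9 was lower in all 5 TBI libraries than in any Sham library. Reads moved to a neighbouring gene are argued against, since genes within 0.1 Mb together changed by -0.164 CPM and did not gain. Of 167 tested genes on 2 levels at least 1 apart on the log2 scale, 121 had low libraries in both groups, among them Hpcal4 and Eif4e, so a quantification step that puts a gene on 1 of 2 levels per library stays open. The levels of 10 genes followed the groups, 9 of them called higher in TBI, as a change between the groups alone would give, and Slc39a9 alone lower; chance would put 0.151 of the 19 others with 5 low and 5 high libraries on the groups, and 1 gene picked for this pattern does not decide. A stretch of chromosome 12 that differs by origin of the animals cannot be told apart from an effect of TBI, because 0 of 46 genes tested within 2 Mb were called against 4.05% elsewhere (Fisher's exact p = 0.264), too few to decide; an effect of the injury stays open too.

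Microglial genes were higher in TBI. A lower share of neurons is argued against: 39 markers of oligodendrocytes, their precursors and endothelial cells had a median log2 change of 0.0557 (quartiles -0.05 to 0.17), against 0.77 for the 12 homeostatic microglial markers (quartiles 0.49 to 1.16). More microglia with the same transcripts per cell are argued against as the sole source, since activated minus homeostatic markers differed by 1.31 on the log2 scale between TBI (0.51 ± 0.33) and Sham (-0.81 ± 0.13) with an exact permutation p = 0.0079, the smallest 5 against 5 can give. For neutrophils and lymphocytes, the highest of S100a8, S100a9, Cd3e, Cd3d, Cd79a and Cd79b in TBI was S100a9 at 0.357 FPKM while Cst7 was at 8.51. Each of these blood cell genes had a higher mean in TBI than in Sham, where S100a9 was at 0.0954 FPKM. The choice left out Csf3r and Cd4, the only members of the neutrophil and lymphocyte lists above the expression filter. Csf3r rose (log2 1.84), and Cd4 was at 0.892 FPKM or more in every library. Whether neutrophils and lymphocytes were a main source is therefore not decided by these genes. A low level does not show that such cells were absent or did not increase. A changed state of microglia after the injury and entry of monocytes, whose genes macrophages and microglia share, stay open.

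Ttr was far higher in TBI replicate 1 than elsewhere. Choroid plexus tissue in that library is a candidate source: all 11 other choroid plexus markers had their highest FPKM there, where 1.1 are expected by chance, Aqp1 at 3.74 and Folr1 at 2.21 FPKM among them. A single gene counted wrongly is argued against, since the median ratio of that library to the highest other was 6.38 over those 11 markers. The design names no difference within the TBI group, so no biological explanation was tested.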

How the results depend on the processing

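Of 978 list values under alternative settings 929 kept their side of the threshold, as did 2503 of 2669 values for single genes. Direction had to be kept only where the value was called in the main or the alternative fit, so uncalled values could change sign. Of 108 gene counts 74 stayed within 1.5 times. All 77 called genes picked by the naming rule kept their sign in each of the 27 settings that tested them, and 59 of them their call in every setting but the rank-sum test. Counts divided by 4, limma-trend on log2(FPKM + 1), edgeR with the replicate block and the omission of small RNA genes were added after seeing the data. Unless a reason is given, the cause was not tested.

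The number of lower genes (77) was 43 with no filter, 48 with the filter of 2 FPKM, 229 in DESeq2, 42 in limma-trend on log2(FPKM + 1) and without trend, 39 with the pseudocount of 0.1, 27 rescaled to TPM and 40 with robust fitting. The number of higher genes (582) was 337 with the filter of 2 FPKM, where 11731 genes were left to test. Higher genes with a fold of 2 or more (238) were 94 with that filter, 84 in limma-trend on log2(FPKM + 1), without trend and with robust fitting, 82 with median-of-ratios, 78 with quantile normalization and 91 with array weights; a pseudocount of 1 shrinks folds of low genes by construction. Lower genes with a fold of 2 or more (5) were 10 in DESeq2. The exact rank-sum test called 0 genes higher and 0 lower, 0 and 0 at a fold of 2, with 1978 genes at an unadjusted p under 0.05; its smallest p with 5 against 5 is 0.00794, which 1033 genes reached and 2590 would need to reach, so it says nothing on stability.

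With the replicate number as a block, limma-trend called 443 genes higher and 25 lower, of which 79 and 6 had a fold of 2 or more, and edgeR 373 higher and 29 lower, of which 203 and 4 had. The block gave the inhibitory neuron list 0.0352, the endothelial list 0.0388, the mural list 0.0649 and the erythrocyte list 0.0352 in limma, and the erythrocyte list 0.0205 in edgeR. Deviations of TBI and Sham libraries with the same number correlated at 0.0016, 0.165, 0.112, -0.141 and 0.0729, and 1 of 5 was highest with its own number, so the numbers do not appear to pair the mice. In 1 or both block fits calls were lost, among them those of Ccl3, Ccl5, Ccl12, Egr1, Gbp2, Ggta1, Mlc1, Pcsk1, Tap1, Tlr1, Cdh5, Etv1, Ptgs2 and Rims1.

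With no filter the lymphocyte list turned to higher in TBI (adjusted p = 0.00626) with 14 members in place of Cd4 alone, of which 0 passed; the A2-type list reached 1.55e-11, proliferation 6.13e-05 and erythrocytes 0.0302. With the filter of 2 FPKM, which leaves fewer members, A2-type genes gave 0.0174, microbial sensing 0.0826, mural 0.0573 and axon injury 0.0363. DESeq2 size factors gave the A2-type list 0.0492 and fry gave it 0.00232. The endothelial list passed in DESeq2 (0.0470), limma-trend on log2(FPKM + 1), without trend and robust (0.0396 each), with the pseudocount of 0.1 (0.0391), quantile normalization (0.0441) and array weights (0.0284). Quantile normalization gave cortical layers 0.0742 and mitochondrial genes 0.212, and fry gave voltage-gated channels 0.0555 and mitochondrial genes 0.0562. An estimated correlation gave homeostatic astrocytes 0.0644, excitatory synapse 0.164, voltage-gated channels 0.190, immediate early genes 0.117, mural 0.284, extracellular matrix 0.0872, cell death 0.0660, cholesterol synthesis 0.0644, cortical layers 0.118 and mitochondrial genes 0.301.

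Leaving out 1 library at a time, lower genes ranged from 37 to 84 (37, 42, 41 and 47 without TBI replicates 1, 2, 3 and 5; 45, 42 and 45 without Sham replicates 1, 2 and 3), and those with a fold of 2 or more from 5 to 9 (9 without TBI replicate 4, 8 without Sham replicate 4). The A2-type list ranged from 0.0158 to 0.133, passing without TBI replicates 1 and 5 (0.0158, 0.0463) and Sham replicates 1 and 2 (0.0376, 0.0388). Proliferation ranged from 0.0441, without TBI replicate 2, to 0.35, and erythrocytes from 0.00917 to 0.406, passing without TBI replicates 2 and 3 (0.00917, 0.0236). Inhibitory neurons ranged from 0.0411 to 0.349, passing without TBI replicate 5 (0.0463) and Sham replicate 1 (0.0411). Cortical layers ranged from 0.0150 to 0.135, failing without TBI replicates 2 and 4 (0.135, 0.0709) and Sham replicates 3 and 4 (0.0588, 0.0507).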

Other observations

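The test in this part, of Cd4 against striatal markers, was chosen after the values were seen. Members of the lists below the expression filter were examined in the fit without a filter, over 32852 genes, where 18 of 114 rose, 0 fell and 96 did not pass. The complement gene C3 went from 0.0287 ± 0.0531 to 1.42 ± 0.820 FPKM (log2 5.48, edgeR adjusted p = 0.012), the iron-binding protein Lcn2 from 0.0925 ± 0.0626 to 0.814 ± 0.419 (log2 3.04, adjusted p = 0.0083), and the transglutaminase Tgm1 from 0.0478 ± 0.0340 to 1.07 ± 0.558 (log2 4.40, adjusted p = 0.0039). The integrin Itgax rose from 0.0501 ± 0.0235 to 0.643 ± 0.234 FPKM. Sham libraries had 0 counts for the axon regrowth gene Sprr1a, the elastase Mmp12, the monocyte chemokine Ccl2 and Ms4a4c, which were at least 35.7-fold, 33.7-fold, 11.3-fold and 7.60-fold higher in TBI against a floor of 12 counts over the group. Sprr1a had counts in 4 of the 5 TBI libraries. Tlr4, the endotoxin receptor, rose 2.02-fold and Tlr6 and Tlr9 rose too. The A2-type list then had 4 members higher and 1 lower of 12, the neutrophil list Csf3r alone of 10, and the lymphocyte list 0 of 14. In the cytokine list 8 of 19 members were higher, in the monocyte and macrophage list 4 of 15, and in microbial sensing 9 of 21, with 0 lower in each.

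The KEGG term with the smallest p was Staphylococcus aureus infection, in which 16 of 26 genes rose and 0 fell (adjusted p = 0.0327 with an estimated correlation). In Antigen processing and presentation 16 of 48 genes rose (adjusted p = 0.0415 with an estimated correlation). In Steroid biosynthesis 3 of 14 genes fell and 1 rose (camera adjusted p = 0.0263, and adjusted p = 0.409 with an estimated correlation). Among GO terms, voltage-gated potassium channel activity was lower, with 2 of 33 genes called (camera adjusted p = 0.00479, and adjusted p = 0.669 with an estimated correlation).

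TBI libraries differed in the size of the response. The mean of activated microglia genes lay above the Sham mean by 2.66, 1.83, 2.30, 1.51 and 2.24 on the log2 scale in TBI replicates 1 to 5, and that of pan-reactive astrocyte genes by 2.14, 1.82, 2.05, 1.26 and 1.77. TBI replicate 4 was lowest for both, and also for interferon-stimulated genes at 0.98, against 2.35 in TBI replicate 1.

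Cd4, the tested lymphocyte marker, ranged from 0.892 FPKM in TBI replicate 2 to 7.11 FPKM in Sham replicate 3. Over the 10 libraries it followed the mean of the 10 striatal neuron markers, with Pearson's r = 0.962 (permutation p = 7.0e-05) and Spearman's rho = 0.939 (permutation p = 1.3e-04). Without the 2 libraries farthest from the median of the striatal mean, r was 0.917 (permutation p = 0.0027). The relation was noticed in these same values before it was tested, so the p values do not account for that choice. The most abundant striatal marker, Penk, ranged from 71.8 to 324.7 FPKM. Whether a varying amount of striatal tissue in the dissected piece accounts for the spread of Cd4 is left open, and other sources of Cd4 were not tested.

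The gene Nnt has 2 entries in the table at nearly the same place on chromosome 13. ENSMUSG00000116207 was at 0 FPKM in Sham replicates 3 and 4 and from 3.97 to 5.12 in the other 8 libraries, and ENSMUSG00000025453 was at 2.40 and 2.74 FPKM in those 2 libraries and from 0.195 to 0.739 in the others. Neither entry was called between the groups (edgeR adjusted p = 0.773 and 0.257).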
